A study of Caenorhabditis elegans with 4 samples.

How the data were processed

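Synchronised L1 larvae of strain OP77 were grown in liquid culture with bacteria at 20 °C and crosslinked with 2% formaldehyde, and the chromatin was sheared by sonication, per the labels' protocols. Immunoprecipitated DNA was size-selected on a gel and made into Illumina libraries. The labels name 4 libraries, and samples were grouped by the descriptions that mark each as input DNA or as ChIP DNA. The labels number the replicates but do not say whether they came from separate cultures.

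The authors deposited 1 list of regions, made with PeakSeq on coordinates of WormBase WS180, per the file headers and its source column. The list is named as combined, it carries no value per library, and the only measured value of a region is the q value given by the authors' peak caller. The aligner, the version of PeakSeq, the scaling of ChIP against input and the distance at which neighbouring regions were joined are not given in the sources used here. Some properties were checked on the list. All q values were under 0.01, no regions overlapped, and the smallest gap between neighbours was 200 bp, so regions nearer than that had been joined or never arose. The q value times the line number never decreased down the list (tolerance 1e-09 on the log10 scale), the form of a p-value multiplied by the number of tests and divided by rank. This product took 1924 distinct values over the 2715 regions, so many regions shared 1.

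The depth of sequencing is unknown, so no read-count interval could be given for any region. Intervals on shares of regions are 95% exact (Clopper-Pearson) binomial intervals over regions and do not include variation between animals or libraries. Whether regions were called on pooled reads or called per replicate and then merged is not given in the sources used here. With no value per replicate, no region has a replicate check.

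Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Widths count both end bases, and positions are midpoints. Chromosome lengths of WS180 were not used here. In their place stands the span from the first to the last region of each chromosome, which is somewhat shorter than the chromosome. On X it begins at 329930. The share in the middle 33.3% of the autosomal spans was tested with a two-sided exact binomial test. Spacing was tested against 10000 uniform placements per chromosome, which may overlap, unlike the called regions. The relation of width and −log10 q was tested with 100000 permutations. The tests of chromosomes against each other, the width by chromosome and the tests on 1 Mb windows were added after the data were examined, and so were the left and right parts of chromosomes, every alternative on the density of chromosome I, the exclusion of regions of 50 bp or less or of the 2 widest regions, leaving out 1 autosome at a time, and placements within 1 Mb windows. The explanations weighed in the closing section were also chosen after the list was examined. The share of regions on X, given without a test of its own, and the tests of the autosomal central share, of spacing and of width against significance were fixed before the data were examined. The alternatives fixed with them were a stricter q value, the more significant 50% of the list, merging of regions 200 or 1000 bp apart, the middle 50% of the span, covered bases in place of regions, and leaving out the 5% widest regions.

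The rule for named items, set beforehand, took the 25 most significant regions with their genes, or the 10 most significant by coordinates where no gene annotation of the same build could be used. The second case applied. Regions of rank 13 and 15, the broad regions of rank 91 and 1073, and the dense stretches were chosen after their values were seen. The gene table at hand belongs to another assembly, WBcel235, and its coordinates were not set against WS180. The location of regions relative to genes, the gene lists, the forkhead motif and regions around the transgene's own genes are therefore not analysed here.

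The tests were run on simulated data, of 2715 regions for the spacing and correlation tests and of counts per window for the window test. With uniform placement, the spacing test passed 0.05 in 1 of 40 simulations, with a mean ratio of 0.99. It passed in 40 of 40 when a share of the regions was moved to within 5 kb of another. The mean ratio was then 0.38, a stronger grouping than the 0.66 observed. The window test passed in 0 of 40 simulations of equal density and in 40 of 40 with chromosome I denser. These counts were drawn independently for each window, so they do not show how the test behaves when neighbouring windows are alike. The correlation test passed in 2 of 40 simulations of unrelated values and in 40 of 40 of related ones.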

Results

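Binding of UNC-130, a forkhead-domain transcription factor of Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in fed hermaphrodites of the first larval stage (L1). The strain, OP77, carries an integrated transgene that makes UNC-130 fused to green fluorescent protein (GFP), and the fusion protein was captured with an affinity-purified goat antibody to GFP. There were 2 ChIP libraries and 2 libraries of input DNA, 1 of each from replicates 1 and 2. The question put to these libraries was where in the genome of L1 animals UNC-130::GFP is bound. The processed data are 1 list of regions, named as combined and without values per library, so no value could be tied to a single library, replicates could not be compared, and the read depth behind each region is unknown. Each region has a chromosome, a start and an end on WormBase release WS180 and a q value assigned by the authors with PeakSeq, a peak caller.

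UNC-130::GFP was called at 2715 regions on the 6 nuclear chromosomes, which together covered 1.34 Mb. The median region was 378 bp wide, and the 25th and 75th percentiles of width were 283 and 574 bp. The widest region spanned 9653 bp and the narrowest 1 bp. In all, 201 regions (7.40%) were at least 1000 bp wide and held 26.1% of the covered bases, and 127 regions (4.68%) were 50 bp wide or less. Every q value was under 0.01, with a median of 9.24e-04. A q value at or under 0.001 was reached by 1404 regions, one at or under 1e-05 by 539, and one at or under 1e-10 by 88.

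The 3 most significant regions were all on the X chromosome. The first lay at X, 6736302 to 6745954, and was also the widest of the list (9653 bp, q = 3.82e-39). The second lay at X, 16929346 to 16931886 (q = 1.42e-36), and the one of rank 3 at X, 1503560 to 1505229 (q = 1.72e-31). Chromosome IV held the fourth, at 3652215 to 3654628 (q = 1.23e-30), and the seventh, at 8526769 to 8529402 (q = 7.04e-24). Chromosome I held the fifth, at 7078952 to 7084135 (q = 7.41e-30), and the eighth, at 9380113 to 9384368 (q = 1.22e-23). Chromosome V held the sixth, at 723708 to 728354 (q = 8.67e-30), and the tenth, at 12548663 to 12550577 (q = 2.90e-22). The ninth lay on chromosome II at 11281090 to 11281840 (q = 6.12e-23). It was 845 bp from the region of rank 13, at 11279519 to 11280244 (q = 3.94e-21). The tenth was 1029 bp from the region of rank 15, at 12551607 to 12553741 on chromosome V (q = 2.83e-20). Counted from edge to edge, 20 of the 25 most significant regions had another called region within 5 kb (80%, exact binomial interval 59.3% to 93.2%). Regions that neighbour each other, as ranks 9 and 13 do, both count, so the interval is approximate. The share was 64% of the 50 most significant, 55% of the first 100, 50% of the first 250 and 40.5% of all 2715 regions. These sets are nested, and more significant regions were also wider. No share under random placement is given for them, and neither width nor splitting of broad regions was allowed for.

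Bound regions were densest on chromosome I and sparsest on chromosomes IV and V. Chromosome I held 627 regions, 23.1% of all (95% exact binomial interval 21.5% to 24.7%), although the span from its first to its last region was 15.1% of the summed spans. Its density was 41.8 regions per Mb, 1.69 times the 24.7 per Mb of the other chromosomes together. The density was 30.4 per Mb on chromosome III (419 regions), 26.7 on X (463), 26.3 on II (400), 21.3 on IV (370) and 20.9 on V (436). The X chromosome held 17.1% of the regions (15.7% to 18.5%) and 17.4% of the span.

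The chromosomes were tested against each other after the counts had been seen. In complete windows of 1 Mb, chromosome I held 41.7 ± 10.7 regions (SD over 15 windows) and the other chromosomes 24.5 ± 8.13. All 15 windows of chromosome I, with 28 to 61 regions each, lay above that mean of the others. When windows were permuted between chromosomes, two-sided and adjusted over the 6 chromosomes by Benjamini-Hochberg, chromosome I was higher (adjusted permutation p = 6e-05, from the smallest p that the permutations can give). Chromosome IV (21.6 per window against 28.3 elsewhere, adjusted permutation p = 0.0324) and chromosome V (21.1 against 28.7, adjusted permutation p = 0.00864) were lower than the rest. The rest included the dense chromosome I, which raises its mean, and neither chromosome was compared without it. Chromosome X had 25.5 regions per window against 27.5 elsewhere, which did not pass the test (adjusted permutation p = 0.569), nor did chromosomes II (0.655) and III (0.334). A window next to another is not independent of it, so these p-values are approximate.

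**Figure D1:**
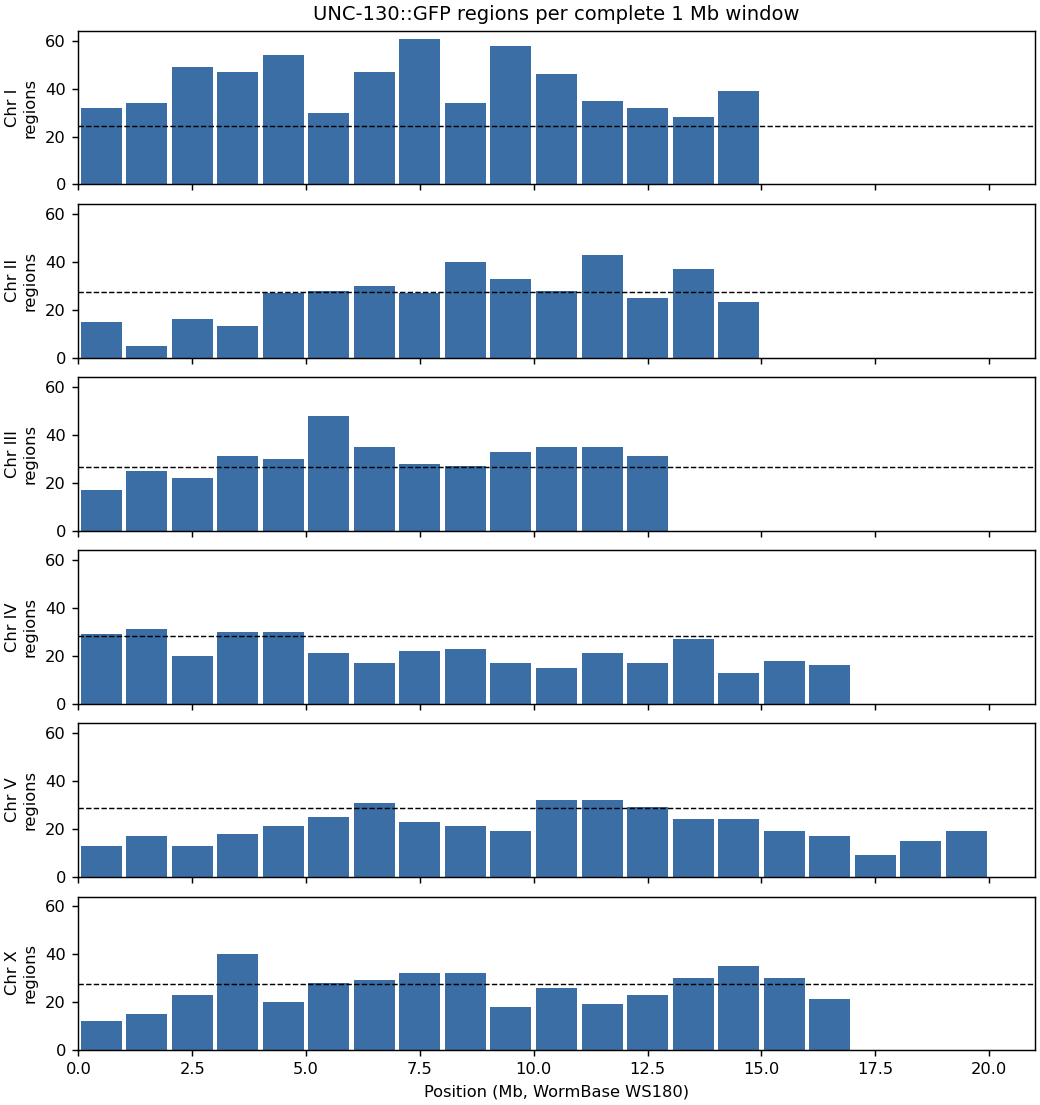
Regions (vertical axis, count) in each complete 1 Mb window along the 6 chromosomes (horizontal axis, position in Mb on WS180); the dashed line in each panel is the mean per window of the other 5 chromosomes. The 15 windows of chromosome I hold 28 to 61 regions and all lie above the mean of 24.5 for the others.

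Regions also differed in width between chromosomes. The median width was 414 bp on X against 370 bp on the autosomes, a difference of 44.0 bp (permutation test, adjusted p = 0.0018). It was 353 bp on chromosome I against 385 bp elsewhere (adjusted permutation p = 0.0201). For chromosomes II to V the difference from the rest did not pass the test. No chromosome passed the same test for the median of −log10 q, where the smallest adjusted permutation p was 0.151. These tests permuted single regions and take them as independent, although neighbouring regions lay close together, and were not repeated on windows.

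Over the autosomes together, bound regions were somewhat denser in the middle 33.3% of the span than in the outer parts. The middle 33.3% of the span held 834 of 2252 autosomal regions, 37.0% (35.0% to 39.1%), against the 33.3% that even spacing gives (two-sided exact binomial p = 2.25e-04). The share was 41.3% on chromosome V (p = 5.39e-04, exact binomial, adjusted over the 6 chromosomes 0.00324) and 39.8% on chromosome II (adjusted exact p = 0.0238). On chromosome II the middle part, with 159 regions, did not exceed both arms, since the right 33.3% of the span held 162 and the left 33.3% held 79. On chromosomes I (36.7%), III (36.8%), IV (30.0%) and X (32.4%) the share did not pass this test. The exact binomial test takes regions as independent, although neighbouring regions lay close together. With whole 1 Mb windows permuted, the autosomal centres held 4.58 more regions per window than the outer parts (two-sided permutation p = 0.0168). Windows were permuted singly, although neighbouring windows are not independent and each centre is 1 unbroken stretch, so this p-value is approximate too. This permutation was not run for single chromosomes, so the results for chromosomes V and II rest on the exact binomial test alone.

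Bound regions lay closer to each other than random placement gave. The median distance from the midpoint of a region to the nearest other midpoint was 8.10 kb, against 12.3 kb (95% range 11.5 to 13.1 kb) in 10000 uniform placements of the same number of regions on the same chromosomes. The ratio was 0.66 (two-sided permutation p = 2e-04, the smallest that the random placements can give). In the deposited list 38.1% of the midpoints had another midpoint within 5 kb, against 24.9% in the placements. The densest 100 kb stretch, at 7.0 to 7.1 Mb of chromosome I, held 14 regions, among them the one of rank 5. Next came 2.6 to 2.7 Mb of chromosome I with 12 regions. The stretches with 11 each lay on chromosomes I (9.1 to 9.2 and 10.1 to 10.2 Mb), III (5.1 to 5.2 and 5.8 to 5.9 Mb) and V (3.6 to 3.7 Mb).

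**Figure D2:**
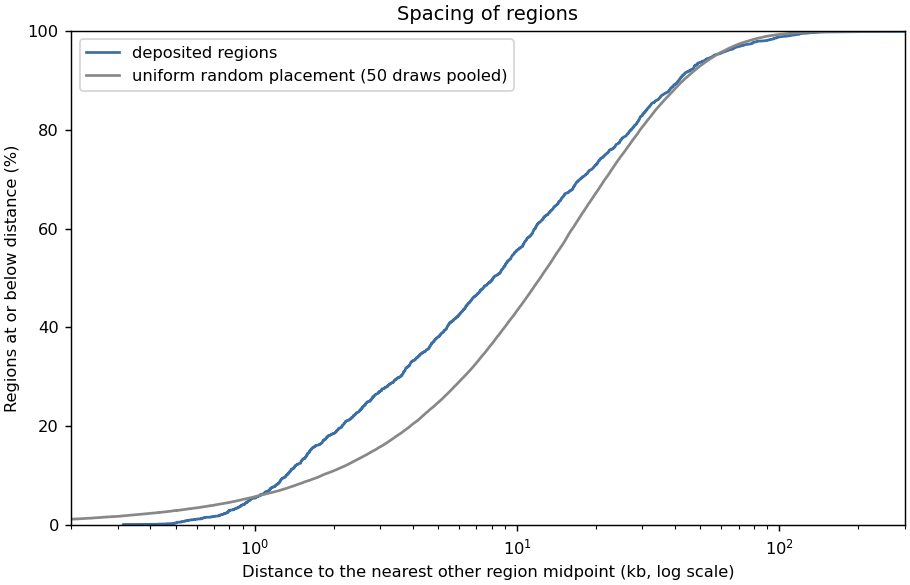
Cumulative share of regions (vertical axis, %) by the distance from a region's midpoint to the nearest other midpoint (horizontal axis, kb, log scale), for the deposited regions and for uniform random placements. The deposited regions reach 38.1% at 5 kb, and the placements 24.9%.

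Wider regions were more significant. Across the 2715 regions, width and −log10 q had a Spearman's rho of 0.39 and a Pearson's r of 0.49 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 5% widest regions Pearson's r was 0.29 and Spearman's rho 0.37. Regions of 1 list are not independent replicates. Width and q value also come from the same peak call, so the relation describes the list and need not be a property of binding. The median width was 505 bp in the most significant 25% of the list, 403 bp in the next 25%, 330 bp in the next and 296 bp in the least significant 25%. Of the 201 regions of at least 1000 bp, 109 were in the most significant 25% of the list. No region of 50 bp or less was among these, and the 2 least significant parts of the list held 54 and 60 of them. The second-widest region, of 7795 bp on chromosome II at 10546519 to 10554313, ranked 91 (q = 1.39e-10). A broad region of lower significance, of 3353 bp on chromosome IV at 14610397 to 14613749, ranked 1073 (q = 3.91e-04).

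**Figure D3:**
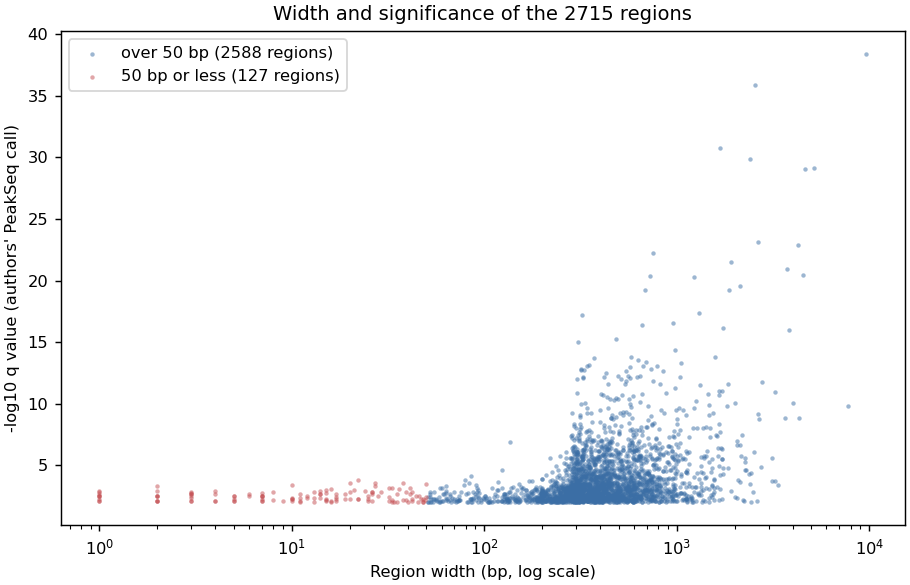
Width of each region (horizontal axis, bp, log scale) against −log10 of its q value as called by the authors (vertical axis); regions of 50 bp or less are in red and the others in blue. The widest region, of 9653 bp, is also the most significant, and the 127 narrow regions all lie near the bottom, with no q value under 1.66e-04.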

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

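Alternatives were compared for the number and width of regions, the X share, the central share, the spacing, the relation of width to significance and the density on chromosome I. The number of regions fell to 1404 with a q value at or under 0.001 and to 1357 in the more significant 50% of the list, by construction, and the median width rose to 438 and 442 bp. Without regions of 50 bp or less, 2588 regions remained with a median of 391 bp, and merging at 1000 bp left 2500. Merging at 200 bp joined 1 pair. The X share stayed between 17.2% and 18.3% under its 4 alternatives. The central share of the autosomes stayed past the threshold of the exact binomial test under all 4 (p between 1.19e-07 and 0.0162). It was between 36.3% and 37.8% for the middle 33.3% of the span and 55.6% for the middle 50%. Leaving out 1 autosome at a time gave 36.01% to 38.4%, with exact binomial p of at most 0.0158. That test takes regions as independent, and the permutation of 1 Mb windows was not repeated for any of these settings. The ratio of observed to random spacing ran from 0.67 to 0.79 under its 4 alternatives, each at the smallest p its 2000 placements can give (0.001). Spearman's rho ran from 0.37 to 0.39, and Pearson's r was 0.29 without the 5% widest regions against 0.49 with them. The 1 Mb density ratio of chromosome I to the others ran from 1.51 in the least significant 25% of regions to 1.90 in the more significant 50%, against 1.70 over all. Enrichment or read counts in place of q values could not be tried, since the list holds neither, and the gene and motif comparisons were not run at any setting. No paired analysis was possible because the list is a combined one with no value per replicate, and for the same reason no replicate could be left out.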

Other observations

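The tests of lenient calling on chromosome I and of shared products of q value and line number were chosen after their results were seen. So were the comparisons of the left and right parts of chromosomes. The other tests were chosen after the list had been examined but before their own results were seen. Regions were spread unevenly along some chromosomes. On chromosome II the right 33.3% of the span held 162 regions and the left 33.3% held 79, a ratio of 2.05. On chromosome IV the left part held 159 and the right part 100, a ratio of 1.59. Both differences passed an exact binomial test adjusted over the 6 chromosomes (adjusted p = 8.9e-04 on IV and lower on II). Neither passed when whole 1 Mb windows were permuted, with an adjusted permutation p of 0.0723 for each. The other 4 chromosomes passed neither test. Chromosome II held as few as 5 regions in a window of 1 Mb and as many as 43.

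The higher density of regions on chromosome I held under each restriction tried. The density ratio to the other chromosomes over 1 Mb windows was 1.70 (95% bootstrap interval 1.48 to 1.97). Splitting of broad regions into more pieces there would bring it near 1 once neighbours were merged, but it was 1.58 (1.40 to 1.78) with gaps of 5 kb or less merged. Narrow calls were not the source, with a ratio of 1.70 (1.45 to 2.00) without regions under 200 bp. A few dense stretches were not the sole source, since all 15 windows held 28 to 61 regions, above the mean of 24.5 elsewhere. Without the 3 densest windows the ratio was 1.54 (1.36 to 1.75). Those counts already kept it above 1, so this adds no separate test. A more lenient call on chromosome I, as a scaling of ChIP to input made per chromosome could give, stays open: the ratio was 1.83 (1.51 to 2.22) in the most significant 25% of regions and 1.51 (1.27 to 1.80) in the least significant 25%, and these intervals overlap. No biological explanation was tested, since gene positions on WS180 were not used here.

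The 127 regions of 50 bp or less are shorter than the DNA fragments that such a library is made of, and a candidate explanation is that they were called on few reads. Few reads give few possible p-values. Of these regions, 93.7% shared their product of q value and line number with another region, against 58.3% of 127 wider regions matched on q. This is a difference of 35.4 percentage points (26.0 to 44.9). That sharing was seen first and prompted the explanation, so it cannot support it, and with no read counts in the list the explanation stays open. Another explanation is that narrow regions are edges of neighbours. No excess of close neighbours was seen, since 7.87% of them had another region within 1 kb against 12.6% of the matched ones. The difference was -4.72 percentage points (-11.8 to 2.36, permutation p = 0.3). The list holds no gap under 200 bp, so edges nearer than that could not be seen if the caller joined them, and for these the comparison cannot decide.

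A last pattern is the grouping of regions. If the caller had only split broad bound stretches, no excess was predicted at distances of 2 to 10 kb between neighbouring midpoints. There were 672 such distances, against 540 (505 to 576) in placements that keep the density of each 1 Mb window. Pieces of a broad stretch can themselves have midpoints that far apart, as with the widest region (9653 bp) and its neighbour 233 bp away. The count therefore cannot settle whether splitting alone is enough. Regions still lay closer than uniform placement gave with gaps of 1000 bp or less merged (ratio 0.79). Splitting at gaps that short is therefore not enough alone to give the spacing seen against uniform placement. Placements that keep the density of each 1 Mb window were not run on the merged list. On the unmerged list they moved the ratio from 0.66 to 0.68. The 652 regions with another within 2 kb had a higher median −log10 q than the other 2063, 3.27 against 3.00, a difference of 0.27 (0.11 to 0.44, permutation p = 2e-04 within chromosomes), but they were also wider, with a median of 453 bp against 358 bp. Within 10 classes of width the mean difference was 0.17 (-0.05 to 0.40, permutation p = 0.137), so whether stronger regions lie in groups or the difference may come from width alone stays open.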
